A study of Caenorhabditis elegans with 11 samples.

How the data were processed

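RNA of whole Caenorhabditis elegans hermaphrodites was measured on Affymetrix C. elegans genome arrays, 1 array per sample. Per the labels, the worms carried glp-1(e2141), a temperature-sensitive allele of the Notch receptor that keeps germ line stem cells dividing. Embryos came from 15 °C, and plates were kept at 25 °C, where the mutant is sterile, from the first larval stage for 8 days. Plates of 10 cm held either 500 hermaphrodites or 250 hermaphrodites with 250 wild-type males, so that the total number of worms was matched and the number of hermaphrodites was not. Males were taken off on day 8, and RNA came from 200 hermaphrodites per sample. The labels give utx-1 RNAi for part of the samples and no RNAi for the others. They name OP50 bacteria on the plates and give neither an empty-vector control nor the way in which the RNAi was delivered.

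The 11 arrays were put into 4 groups by their titles: glp-1 without males (n = 3), glp-1 with males (n = 3), utx-1 RNAi without males (n = 3) and utx-1 RNAi with males (n = 2, replicates 1 and 3). Per the labels, the samples of a condition came from independent experiments, and 1 sample of utx-1 RNAi with males gave too little RNA. The replicate number in the description differs from that in the title for 2 utx-1 RNAi arrays (replicate 2 without males and replicate 3 with males), and the title was followed.

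The deposited values are log2 expression values, 1 per probe set and array, which the authors made with RMA, per the submitters' processing notes. The version and settings of RMA, and whether all arrays were processed together, are not given in the sources used here. The table held 22625 probe sets with values from 1.83 to 13.69, the array medians lay between 3.78 and 3.98, and at equal rank the arrays differed by at most 0.28. RMA compresses the changes of dim probe sets, so a log2 change can understate the change in RNA. The number of arrays limits the precision.

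The 77 control probe sets were left out, which left 22548 for testing. In the platform's annotation 20766 of these had 1 gene symbol, 887 had several and 895 were not listed. Symbols of 20701 probe sets were updated by gene identifier through the RefSeq gene table of assembly WBcel235, which was used for names only. No gene was named from a probe set with several symbols. Probe sets ending in _s_at or _x_at can bind transcripts of related genes.

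A model with 1 mean per group was fitted to the log2 values of all 11 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings). It had 7 residual degrees of freedom and 4.84 from the prior. The 6 comparisons were the effect of males without RNAi, the effect of males under utx-1 RNAi, the average of both, the effect of utx-1 RNAi without males, the effect of utx-1 RNAi with males, and the interaction, which is the males effect under utx-1 RNAi minus the males effect without RNAi. P-values were adjusted by Benjamini-Hochberg over the 22548 probe sets within each comparison, with a threshold of 0.05. The words rose, fell and changed are used for results past that threshold. Each adjusted p of a gene is limma's, and ± gives the standard error of the fit unless SD is named.

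Gene lists were tested with limma's camera at its preset inter-gene correlation of 0.01, on the brightest probe set of each of 17118 genes, with adjustment over the 37 lists of a comparison. Camera asks whether a list moved relative to all other genes. With the correlation estimated from the data, 0 of the 37 lists passed in each of the 6 comparisons, against 1 to 3 lists at an unadjusted p under 0.05, and that adjusted p is given beside the lists. Members past the threshold were counted after adjustment over all probe sets and, separately, adjusted over the list alone.

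The groups, comparisons, tests, lists and naming rule were fixed before the data were examined. The rule names, per comparison, up to 12 genes with the largest rise and up to 12 with the largest fall among probe sets with 1 symbol, an adjusted p under 0.05 and no overlap between the arrays of both groups, taking the probe set with the smallest p for each gene. For the interaction and the averaged effect the overlap condition was left out. Of the 2661 probe sets that changed with males without RNAi, 2652 did not overlap between groups. Selection by p makes this nearly certain, so it adds no support to the calls. For probe sets not selected by p, chance gives 10% for 3 arrays against 3. The rule adds up to 4 members of each list with the smallest p, and utx-1, glp-1, sod-3, vit-2, ins-11, ins-7, nlp-7, unc-25, snf-11 and jmjd-3.1 in every comparison. A list uses the brightest probe set of a gene, so a value given for a list member can differ from that of the same gene among the largest changes.

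The procedure was tested on simulated data with the measured means and residual spread of the 22548 probe sets and known changes in a random set of them. In each comparison 67, 67 and 66 probe sets were changed by 0.5, 1 and 2. Errors were drawn independently for each probe set, so the test does not cover batches, correlated errors or changes in a large share of probe sets. For males without RNAi it recovered 64.2% of changes of 0.5 on the log2 scale, 98.5% of changes of 1 and 100% of changes of 2, with 6 false calls among 181. For utx-1 RNAi with males the shares were 46.3%, 94.0% and 100%, with 7 false calls among 167. For the interaction they were 16.4%, 70.1% and 100%, with 10 false calls among 134.

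Alternatives were the replicate number as a block, a fit of only the 2 groups compared, a trended and robust prior, leaving out probe sets below the 40th percentile of mean level, centring arrays on their medians, cyclic loess between arrays, array weights, 1 probe set per gene, the mean over a gene's probe sets for lists, camera with an estimated correlation, and leaving out each array in turn. A fit without both arrays of utx-1 RNAi with males was added after the data had been seen.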

Results

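Expression was measured on 11 arrays from sterile glp-1(e2141) hermaphrodites kept with or without males, with utx-1 RNAi or with none named. The gene utx-1 encodes a demethylase of histone H3 lysine 27. The design asks which transcripts change in hermaphrodites when males are present and whether knockdown of utx-1 alters that response. No empty-vector group is named. In the comparisons of utx-1 RNAi with no RNAi and in the interaction, knockdown of utx-1 therefore cannot be told apart from RNAi treatment as such or from its food. The 9 arrays other than those of utx-1 RNAi with males correlated with each other at r of at least 0.986 across probe sets, which are not independent replicates. Both arrays of utx-1 RNAi with males correlated with each other at 0.995 and with the other 9 at 0.961 to 0.983. The smallest SD of the difference between 2 arrays of a group was 0.171, so no array was a copy of another.

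The knockdown target was lower in every utx-1 RNAi array. Without males, utx-1 fell by 2.47 ± 0.09 on the log2 scale at the dimmer of its probe sets (adjusted p = 1.27e-07, limma). At the brighter one it fell by 6.55 ± 0.36 (adjusted p = 6.09e-06), with 3 arrays in each group. On the linear scale 18.1% and 1.07% of the signal were left. With males, utx-1 fell by 2.15 ± 0.10 and by 4.18 ± 0.40, which left 22.5% and 5.51%. In the arrays without RNAi the brighter probe set had a mean of 12.46, at percentile 99.7 of all probe sets, and the dimmer one a mean of 7.08, at percentile 80.7. Whether the brighter probe set also binds another RNA is not given in the sources used here, which limits what its changes and the 1.07% and 5.51% say about utx-1.

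**Figure D1:**
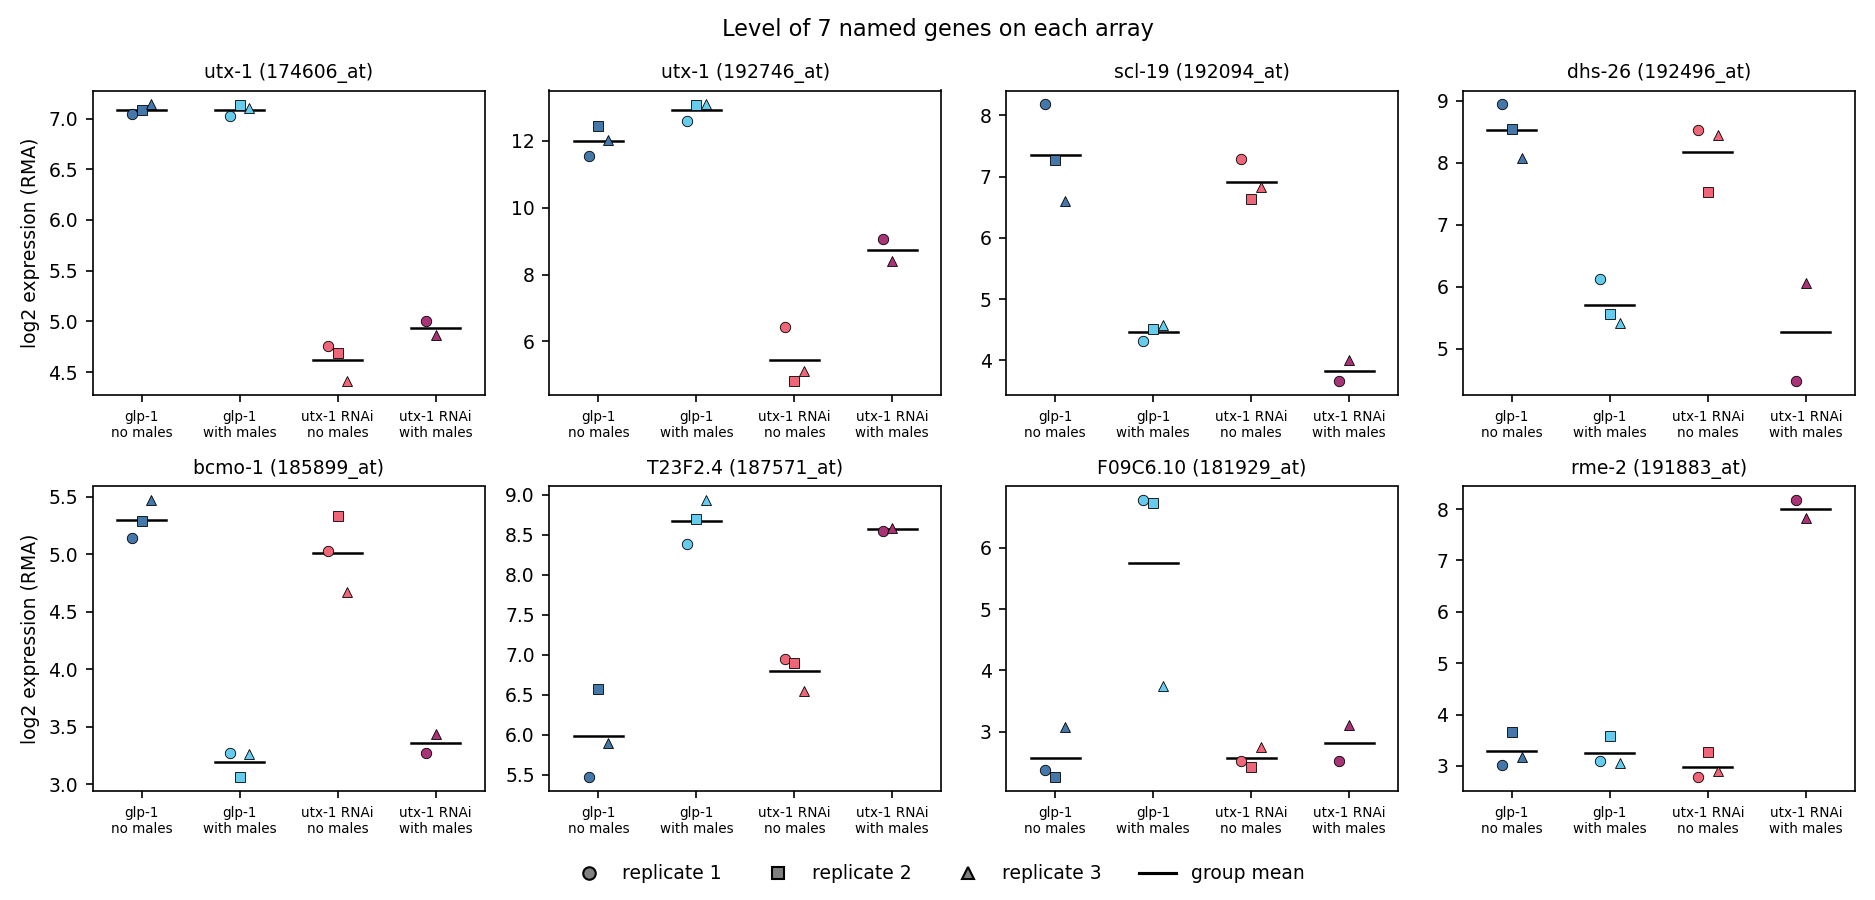
Log2 expression (RMA, vertical axis) of 7 genes on each of the 11 arrays, with utx-1 shown at both of its probe sets. Points are arrays with the shape giving the replicate, and horizontal lines are group means. The dimmer probe set of utx-1 averages 4.62 and 4.93 in the utx-1 RNAi groups without and with males and 7.08 in both other groups, and F09C6.10 reads 6.77 and 6.72 in 2 arrays and at most 3.74 in the others.

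The first comparison asks what males change in glp-1 hermaphrodites without RNAi (3 arrays against 3). The deepest falls were those of the cathepsin B-like protease gene cpr-2, by 2.97 ± 0.61 on the log2 scale (adjusted p = 0.00957), scl-19, by 2.88 ± 0.30 (adjusted p = 0.000456), and the short-chain dehydrogenase gene dhs-26, by 2.81 ± 0.38 (adjusted p = 0.0017). The C-type lectin gene clec-61 fell by 2.41, dlhd-1 by 2.24, the beta-carotene monooxygenase gene bcmo-1 by 2.10 ± 0.15 (adjusted p = 3.37e-05) and C30G12.2 by 2.08. Smaller falls were those of gfi-1 (-1.72), the aspartyl protease gene asp-13 (-1.70), lips-11 (-1.62), Y16B4A.2 (-1.59) and T22B7.7 (-1.56). Among the rises, T23F2.4 gained 2.69 ± 0.23 (adjusted p = 0.000126), the small heat shock gene hsp-16.21 gained 2.57 ± 0.34 (adjusted p = 0.0016) and K11H12.6 gained 2.54 ± 0.26 (adjusted p = 0.000414), each higher in 3 of 3 arrays. The other 9 largest rises were F09C6.10 (3.18), K03D3.5 (2.96), K12H6.9 (2.91), fipr-17 (2.70), clec-197 (2.68), C48B4.12 (2.65), T26A8.3 (2.56), ZK1290.11 (2.48) and the insulin-like gene ins-31 (2.47). Of these, all but C48B4.12 belong to 13 probe sets that were at least 1.5 higher in replicates 1 and 2 with males than in any other array. F09C6.10 read 6.77 and 6.72 in those replicates and 3.74 in replicate 3. C48B4.12 read 7.40, 5.72 and 4.29. With a trended and robust prior the calls of K12H6.9 (adjusted p = 0.0565), C48B4.12 (0.0539), ins-31 (0.0805), clec-61 (0.0565) and lips-11 (0.131) ended, and that of lips-11 reached 0.149 without replicate 1 of glp-1 without males.

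Genes of the mitochondrial respiratory chain fell as a group with males without RNAi. Of 38 members 21 fell and 0 rose (31 fell adjusted over the list alone). Their median was -0.32 (camera adjusted p = 1.17e-13; adjusted p = 0.64 with an estimated correlation). Examples are nuo-6 (-0.41), ucr-2.1 (-0.38), ucr-2.2 (-0.56) and cox-6B (-0.41). Of 147 cuticle collagens 24 fell and 1 rose (30 and 1 adjusted over the list alone). Their median was -0.11 (camera adjusted p = 0.000105; adjusted p = 0.79 with an estimated correlation). The adult collagen gene col-19 and col-118 each fell by 1.24 and sqt-3 by 0.64, while col-116 rose by 0.46. In the propionate shunt and vitamin B12 list 9 of 22 genes fell and 2 rose (11 and 2 adjusted over the list alone). Their median was -0.25 (camera adjusted p = 0.00271; adjusted p = 0.64 with an estimated correlation). Among them were pmt-2 (-0.84), ech-6 (-0.41) and hphd-1 (-0.45), with acdh-2 up by 0.58. Of 177 detoxification enzymes 39 fell and 16 rose (51 and 18 adjusted over the list alone). Their median was -0.087 (camera adjusted p = 0.0262, or 0.00929 to 0.0641 over the other alternatives, the highest without replicate 1 of glp-1 without males; adjusted p = 0.79 with an estimated correlation). The UDP-glucuronosyltransferase genes went both ways, with ugt-63 at -1.41, ugt-16 at 1.84, ugt-9 at 2.01 and ugt-33 at 1.60. The 75 ribosomal protein genes had a median of -0.066 with 1 fall, that of rpl-23A.2 by 0.30, and 0 adjusted over the list alone (camera adjusted p = 0.0218, or 0.000204 to 0.169 over the other alternatives, the highest without replicate 1 of glp-1 without males; adjusted p = 0.893 with an estimated correlation). The call of rpl-23A.2 also ended without that array (adjusted p = 0.124).

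Heat shock, antimicrobial peptide, insulin-like and neuropeptide-like genes were among the lists past the threshold upward with males without RNAi. The lists of the unfolded protein response did not pass, with 2 of 17 genes higher for that of the endoplasmic reticulum (median -0.012, mean 0.026, camera adjusted p = 0.724) and 2 of 9 lower for that of mitochondria (0.092). Nor did FMRFamide-like peptides (0.201), with 0 of 25 past limma's threshold and 1 higher at an unadjusted p under 0.05. Of 9 heat shock genes 4 rose and 0 fell (6 adjusted over the list alone). Their median was 0.43 (camera adjusted p = 0.000515; adjusted p = 0.64 with an estimated correlation). The risers were hsp-16.41 by 0.71, hsp-16.2 by 0.73, hsp-1 by 0.51 and hsp-43 by 0.48. Of 23 antimicrobial peptide genes 7 rose and 2 fell (10 and 2 adjusted over the list alone). Their median was 0.15 (camera adjusted p = 0.00271; adjusted p = 0.79 with an estimated correlation), and cnc-1 was up by 2.16, cnc-4 by 1.07, nlp-30 by 1.04 and nlp-31 by 0.94. Of 24 insulin-like peptide genes 7 rose and 0 fell (8 adjusted over the list alone). Their median was 0.06 (camera adjusted p = 0.00545; adjusted p = 0.64 with an estimated correlation). Risers were ins-4 (1.38), ins-23 (1.12) and ins-22 (0.71). Of 48 neuropeptide-like genes 4 rose and 0 fell, also adjusted over the list alone. Their median was 0.08 (camera adjusted p = 0.0489, or 0.0106 to 0.181 over the other alternatives, the highest without replicate 2 of glp-1 without males; adjusted p = 0.79 with an estimated correlation). The members that rose were nlp-39, by 1.28, nlp-2 by 0.77, nlp-80 by 0.34 and nlp-52 by 0.34. Of 26 histone genes 6 rose and 0 fell (7 adjusted over the list alone; median 0.19, camera adjusted p = 0.00054; adjusted p = 0.64 with an estimated correlation), including his-6 (0.39) and his-72 (0.43). Of 33 proteasome genes 3 rose and 0 fell, also adjusted over the list alone (median 0.16, camera adjusted p = 1.51e-05; adjusted p = 0.79 with an estimated correlation). The risers were rpt-6 by 0.50, pbs-7 by 0.34 and rpt-5 by 0.31. The 23 major sperm protein genes had a median of 0.29, with 0 members past limma's threshold, also adjusted over the list alone, and 6 higher at an unadjusted p under 0.05 (camera adjusted p = 0.000573, or 3.32e-06 to 0.154 over the other alternatives, the highest without replicate 2 of glp-1 with males; adjusted p = 0.79 with an estimated correlation). Their mean level was 4.23 ± 0.15 (SD, n = 3) without males and 4.53 ± 0.32 (SD, n = 3) with males. Single calls that ended in some alternatives were, with the highest adjusted p, hsp-1 (0.0647), rpt-6 (0.0821), pbs-7 (0.0893) and rpt-5 (0.137) without replicate 1 of glp-1 without males. Those of nlp-80 (0.0731), nlp-39 (0.118), hsp-16.2 (0.065) and hsp-43 (0.121) ended without replicate 2 of glp-1 with males, and that of nlp-52 (0.0766) without its replicate 3.

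Of the genes followed in every comparison, the superoxide dismutase gene sod-3 rose by 0.68 ± 0.09 (adjusted p = 0.00176), ins-11 by 0.78 ± 0.21 (adjusted p = 0.0327), ins-7 by 0.74 ± 0.19 (adjusted p = 0.0275) and jmjd-3.1 by 0.39 ± 0.11 (adjusted p = 0.0428). Over all alternatives the adjusted p was 0.000784 to 0.0097 for sod-3, 0.0155 to 0.126 for ins-11, 0.0073 to 0.105 for ins-7 and 0.024 to 0.159 for jmjd-3.1, the last 3 being highest without replicate 1 of glp-1 without males. Not past the threshold were nlp-7 at -0.27 (adjusted p = 0.0785), unc-25 at -0.33 (adjusted p = 0.169), snf-11 at 0.29 (adjusted p = 0.0763), vit-2 at 0.20 (adjusted p = 0.0779) and glp-1 at -0.09 (adjusted p = 0.797). For utx-1 the values were -8.43e-05 at the dimmer and 0.91 at the brighter probe set (adjusted p = 0.133). Over all probe sets, 2661 changed, 1275 higher and 1386 lower, with 167 of the rises and 86 of the falls over 2-fold. The count was 1362 without replicate 1 of glp-1 without males, and 1678 and 1524 without replicates 2 and 3 of glp-1 with males.

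The second comparison asks what males change under utx-1 RNAi (2 arrays against 3). Of the 12 rises named, 4 are in the oocyte and eggshell list and 1 is in the germ cell list. The small heat shock family gene sip-1 gained 6.94 ± 0.37 (adjusted p = 1.18e-07), clec-87 gained 6.69 ± 0.49 (adjusted p = 1.19e-06), and the eggshell proteoglycan genes cpg-2 and cpg-1 gained 6.35 ± 0.28 and 6.14 ± 0.28 (adjusted p = 5.68e-08 for each). At the brightest probe sets of clec-87 and cpg-1 the values were 6.42 and 4.64. The eggshell chitin-binding gene cbd-1 gained 5.48 ± 0.20 and rme-2, the oocyte receptor for yolk, gained 5.01 ± 0.22 (adjusted p = 5.68e-08 for each), each higher in 2 of 2 arrays. The remaining rises of the 12 were cpg-3 (5.48), the germ line translation factor gene iff-1 (5.26), mesp-1 (5.20), the Y-box gene cey-2 (5.10), trcs-1 (5.09) and W05F2.3 (5.06). The falls were led by scl-19 (-3.09 ± 0.34, adjusted p = 4.26e-05), dhs-26 (-2.89 ± 0.43, adjusted p = 0.000501), C30G12.2 (-2.49), ZK512.7 (-2.26), cpr-2 (-2.21) and lips-11 (-2.18). They went on with clx-1 (-2.05), clec-61 (-1.99), sdz-24 (-1.79), ugt-63 (-1.70), Y16B4A.2 (-1.68) and bcmo-1 (-1.65). Of these 12 falls 6 lost their call without replicate 1 of utx-1 RNAi with males: cpr-2 (adjusted p = 0.454), clec-61 (0.392), clx-1 (0.159), lips-11 (0.125), sdz-24 (0.0711) and Y16B4A.2 (0.0629). The first 4 also lost it with the trended prior, while the 12 rises lost it in none.

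Of 29 germ cell genes 28 rose under utx-1 RNAi with males (29 adjusted over the list alone). Their median was 2.19 (camera adjusted p = 6.4e-33; adjusted p = 0.128 with an estimated correlation). Among them mex-5, which encodes a maternal RNA-binding protein, gained 4.60, puf-7 4.83, puf-3 3.49 and htp-3 2.17. Of 13 oocyte and eggshell genes 11 rose, also adjusted over the list alone. Their median was 3.34 (camera adjusted p = 4.43e-16; adjusted p = 0.156 with an estimated correlation). The mean level of the germ cell list was 3.89 ± 0.15, 3.99 ± 0.11 and 3.83 ± 0.17 (SD, n = 3 each) in glp-1 without males, glp-1 with males and utx-1 RNAi without males, and 6.24 ± 0.10 (SD, n = 2) in utx-1 RNAi with males. That of the oocyte list was 5.05 ± 0.25, 5.13 ± 0.11, 4.86 ± 0.24 and 8.30 ± 0.20 in the same order. The gene glp-1 itself rose by 1.31 ± 0.19 (adjusted p = 0.000504) in these arrays. The 23 major sperm protein genes had a median of -0.086 (camera adjusted p = 0.76), with 0 members past limma's threshold and 0 at an unadjusted p under 0.05.

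**Figure D2:**
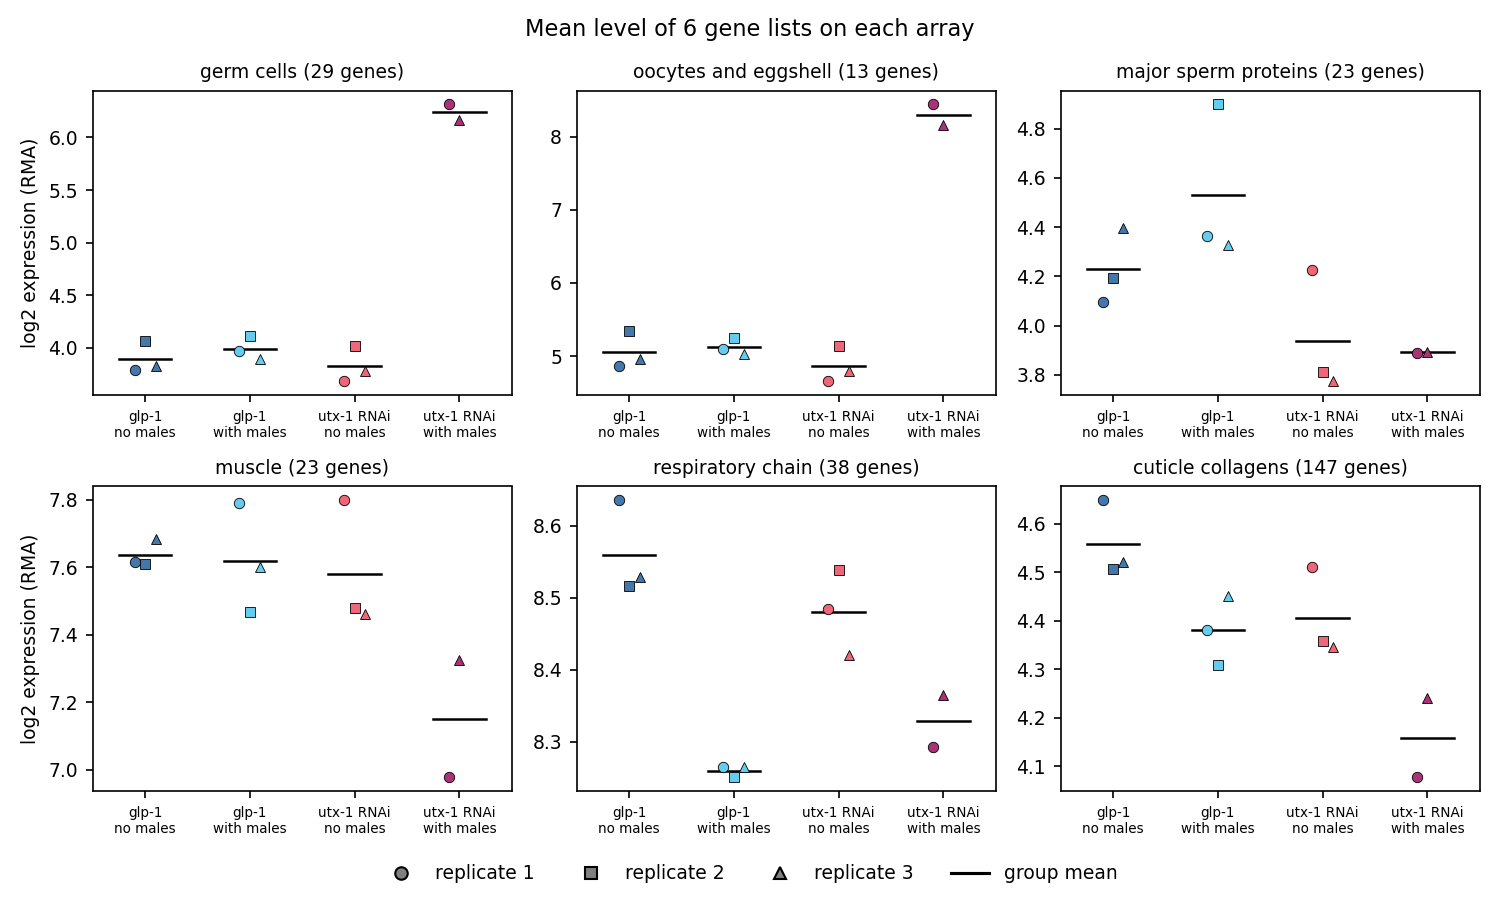
Mean log2 expression (RMA, vertical axis) of 6 gene lists on each of the 11 arrays, with the point shape giving the replicate and horizontal lines for group means. Germ cell genes average 6.24 in utx-1 RNAi with males and from 3.83 to 3.99 in the other 3 groups, and the respiratory chain list averages 8.26 in glp-1 with males against 8.56 without.

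Muscle genes fell in the same arrays in which the germ line lists rose. The values are relative to all RNA on an array, so a larger share of germ line RNA and less muscle RNA cannot be told apart. The same limit holds for the other lists that fell in these 2 arrays, also against glp-1 with males and in the interaction. Of 23 muscle genes 8 fell and 0 rose (11 adjusted over the list alone). Their median was -0.38 (camera adjusted p = 4.26e-05; adjusted p = 0.642 with an estimated correlation). The gene tni-3 fell by 1.18, the myosin gene unc-54 by 0.85, unc-27 by 0.80 and dim-1 by 0.79. The calls of unc-27 (adjusted p = 0.0828) and dim-1 (0.0742) ended without replicate 1 of utx-1 RNAi with males. Of 147 cuticle collagens 34 fell and 0 rose (40 adjusted over the list alone; median -0.16, camera adjusted p = 2.63e-06; adjusted p = 0.642 with an estimated correlation), with col-140 at -1.43 and col-19 at -1.09. Of 177 detoxification enzymes 55 fell and 15 rose (65 and 16 adjusted over the list alone; median -0.16, camera adjusted p = 0.000143; adjusted p = 0.642 with an estimated correlation). Of 38 respiratory chain genes 12 fell and 3 rose (21 and 3 adjusted over the list alone; median -0.23, camera adjusted p = 0.000267; adjusted p = 0.642 with an estimated correlation), with ucr-2.1 at -0.56 and ucr-2.3 at 1.57. Of 262 lysozyme, lectin and saposin genes 41 fell and 9 rose (40 and 9 adjusted over the list alone; median -0.096, camera adjusted p = 0.00468; adjusted p = 0.642 with an estimated correlation), the rises including clec-88 (5.50) and clec-91 (4.80). Of 254 nuclear hormone receptor genes 33 fell and 6 rose (28 and 5 adjusted over the list alone; median -0.089, camera adjusted p = 0.00648; adjusted p = 0.642 with an estimated correlation), among them nhr-103 (-0.58). In the propionate shunt and vitamin B12 list 7 of 22 fell and 1 rose, also adjusted over the list alone (median -0.16, camera adjusted p = 0.0335, or 0.0546 with centred arrays and 0.0177 to 0.0692 over the other alternatives, the highest without replicate 3 of utx-1 RNAi without males; adjusted p = 0.642 with an estimated correlation).

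Among modifiers of histone H3 lysines 27 and 4 under utx-1 RNAi, 5 of 15 genes rose with males and 0 fell (9 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 0.000165; adjusted p = 0.329 with an estimated correlation). Here mes-3 gained 0.62, set-2 0.69 and rbr-2 0.49. These rises, like that of his-74 below, came in the same 2 arrays in which the germ line lists rose. Whether they belong to that signal was not tested. The list also holds utx-1, which rose by 3.28 ± 0.40 at the brighter probe set (adjusted p = 0.000114) and had a value of 0.32 ± 0.10 at the dimmer one (adjusted p = 0.0476). The latter was past the threshold in 3 of 18 alternatives (adjusted p = 0.0135 to 0.319, the highest without replicate 1 of utx-1 RNAi with males). Of 33 proteasome genes 6 rose and 0 fell (2 adjusted over the list alone; median 0.20, camera adjusted p = 0.000137; adjusted p = 0.642 with an estimated correlation), and of 26 histone genes 6 rose and 2 fell, also adjusted over the list alone (median 0.18, camera adjusted p = 0.034, or 0.0115 to 0.1 over the other alternatives, the highest without replicate 2 of utx-1 RNAi without males; adjusted p = 0.642 with an estimated correlation), with his-74 at 1.29. Not past the threshold were sod-3 at 0.13 (adjusted p = 0.425), ins-7 at 0.47 (adjusted p = 0.146), ins-11 at 0.45 (adjusted p = 0.218), nlp-7 at -0.30 (adjusted p = 0.0548), unc-25 at -0.37 (adjusted p = 0.132), snf-11 at -0.05, vit-2 at 0.18 and jmjd-3.1 at 0.16. In all, 4707 probe sets changed, 2671 higher and 2036 lower, with 720 rises and 118 falls over 2-fold. Centring the arrays moved the median of all probe sets by -0.12 and gave 2012 higher and 5553 lower, and without replicate 1 of utx-1 RNAi with males the count was 2028.

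Many genes changed in the same direction with males in both backgrounds, which share no arrays. Among 22548 probe sets 499 rose in both, where independent lists give 151, and 769 fell in both, where they give 125. With a shared estimate of the spread the lists are not independent, and chance can give more than these counts. A further 39 went opposite ways. Of the 2661 that changed without RNAi, 87.3% had the same sign under utx-1 RNAi, and across probe sets, which are not independent, the changes correlated at Pearson's r = 0.385 and Spearman's rho = 0.397. Ranked by the smaller of both changes, an order set after the data were seen, the joint rises were led by cnc-1 (2.16 without and 2.20 under utx-1 RNAi), followed by iff-1 (1.92 and 5.26), E02H9.7 (2.02 and 1.84), K11H12.6 (2.54 and 1.82) and T23F2.4 (2.69 and 1.77). Below these came hsp-16.21 (2.57 and 1.73), F47B8.10 (1.71 and 1.67), the superoxide dismutase gene sod-5 (1.93 and 1.58) and the tyrosine aminotransferase gene tatn-1 (1.76 and 1.56). The joint falls were led by scl-19, dhs-26, cpr-2 and C30G12.2 and included Y105C5B.15 (-1.53 and -1.58), the lysozyme gene lys-2 (-1.45 and -1.61) and dhs-2 (-1.44 and -1.44). Of the calls under utx-1 RNAi, those of cpr-2 (adjusted p = 0.454), cnc-1 (0.0577) and dhs-2 (0.0938) ended without replicate 1 of utx-1 RNAi with males and that of hsp-16.21 (0.075) without its replicate 3. That of iff-1 without RNAi ended without replicate 1 of glp-1 without males (0.0699). In glp-1 with males iff-1 read 7.06, 6.65 and 4.93 in replicates 1, 2 and 3, against 4.74 at the highest in the arrays without males, so its change without RNAi rests on 2 of 3 arrays. Of the 1268 probe sets that changed the same way in both, 31 also passed the interaction test.

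**Figure D3:**
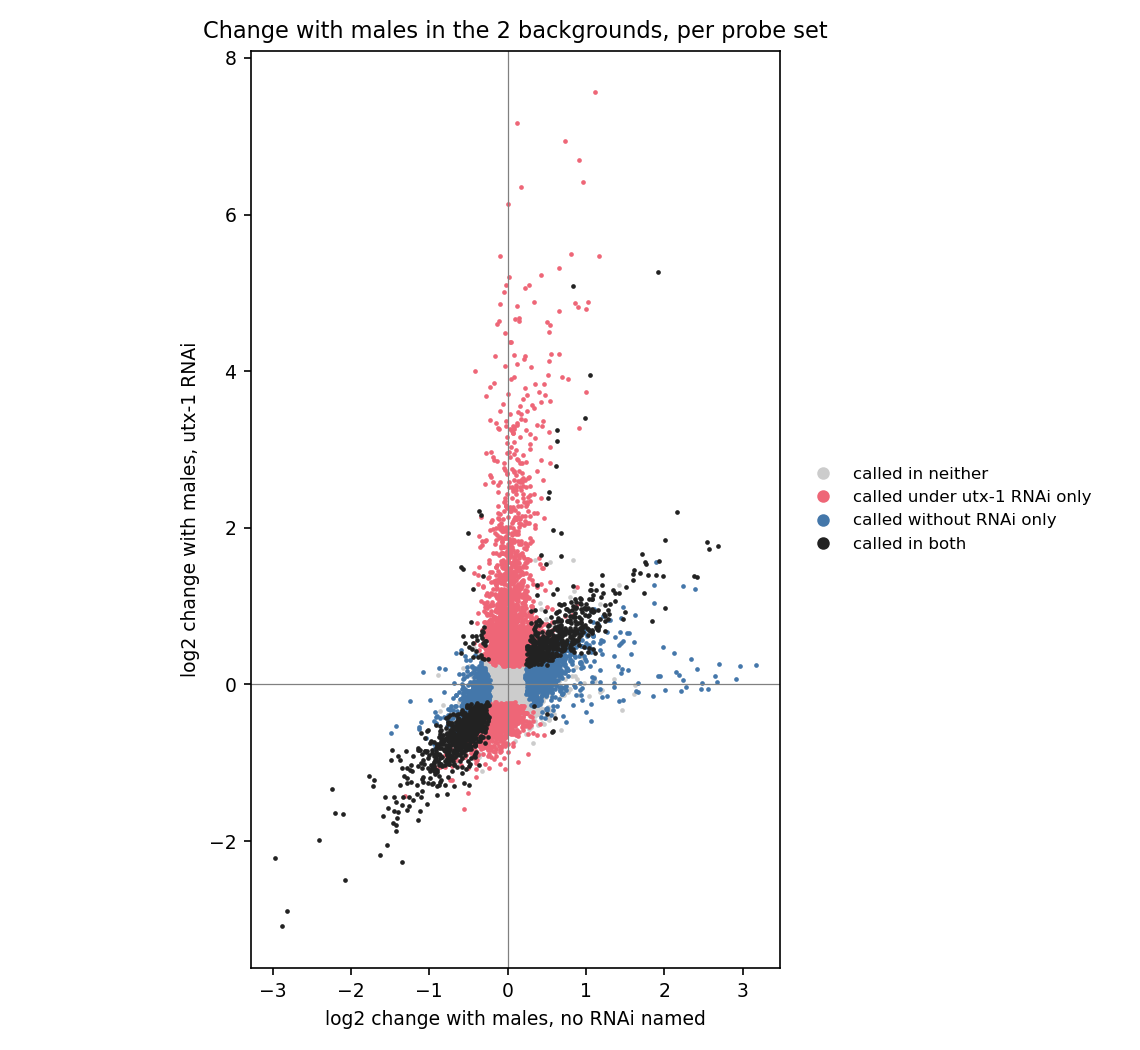
Log2 change with males for each of the 22548 probe sets, without RNAi (horizontal axis) and under utx-1 RNAi (vertical axis), each point being 1 probe set coloured by the comparison in which it passed. The 499 joint rises and 769 joint falls lie in the upper right and lower left parts of the plot, and a column of points near 0 on the horizontal axis reaches high vertical values, such as cpg-2 at 6.35.

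Averaged over both backgrounds, the largest rises with males were sip-1 (3.83 ± 0.25, adjusted p = 1.46e-06), clec-87 (14-fold), iff-1 (3.59 ± 0.33), cpg-3 (3.32) and cpg-2 (3.26). They went on with cpg-1 (3.07), trcs-1 (2.97), the maternal RNA-binding gene pos-1 (2.96), clec-91 (2.90), cyb-2.2 (2.87), F18A1.7 (2.85) and cey-3 (2.71). All 12 also passed the interaction test and 10 of them did not pass without RNAi, where cpg-1 was at 0.01 and cpg-2 at 0.17, so these averages stand mainly for the change under utx-1 RNAi. The falls were scl-19 (-2.98 ± 0.23, adjusted p = 3.35e-06), dhs-26 (-2.85 ± 0.29), cpr-2 (-2.59 ± 0.46), C30G12.2 (-2.29), clec-61 (-2.20), lips-11 (-1.90), bcmo-1 (-1.88), ZK512.7 (-1.80), clx-1 (-1.80), dlhd-1 (-1.78), Y16B4A.2 (-1.64) and sdz-24 (-1.61). Of the genes followed, the averaged test passed for glp-1 (0.61, adjusted p = 0.00436), sod-3 (0.41), ins-7 (0.61), ins-11 (0.62), jmjd-3.1 (0.28), vit-2 (0.19, adjusted p = 0.0143), nlp-7 (-0.28, adjusted p = 0.00819) and unc-25 (-0.35, adjusted p = 0.0306). Of these, glp-1 was at -0.09 without and 1.31 under utx-1 RNAi and sod-3 at 0.68 and 0.13, and both passed the interaction test. It also passed for utx-1 at the brighter probe set (2.09 ± 0.27, adjusted p = 0.000162), whereas the dimmer one had 0.16 ± 0.07 (adjusted p = 0.118) and snf-11 had 0.12 (adjusted p = 0.27). Over the alternatives the adjusted p reached 0.103 for vit-2 with centred arrays. Without replicate 1 of utx-1 RNAi with males it was 0.078 for ins-11, 0.101 for jmjd-3.1 and 0.178 for unc-25. Of 43 fat metabolism genes 14 fell and 3 rose (16 and 3 adjusted over the list alone; median -0.064, camera adjusted p = 0.0258, or 0.0547 with centred arrays and 0.0117 to 0.0582 over the other alternatives, the highest without replicate 3 of utx-1 RNAi without males; adjusted p = 0.566 with an estimated correlation), with the lipase genes lipl-1 at -1.28 and lipl-5 at -1.17 and sbp-1 at -0.57. Of 38 respiratory chain genes 28 fell and 2 rose (30 and 2 adjusted over the list alone; median -0.28, camera adjusted p = 3.78e-09; adjusted p = 0.49 with an estimated correlation). Germ cell genes (28 rose, 29 adjusted over the list alone) had a median of 1.13 (camera adjusted p = 4.13e-24; adjusted p = 0.273 with an estimated correlation). For oocyte and eggshell genes, 11 of which rose, also adjusted over the list alone, it was 1.64 (camera adjusted p = 1.06e-12; adjusted p = 0.273 with an estimated correlation). Without RNAi neither list passed, with medians of 0.034 and 0.093 (camera adjusted p = 0.395 and 0.372). The other lists past the threshold upward were the proteasome (15 rose, 23 adjusted over the list alone, median 0.16), histones (13 rose and 2 fell, with his-68 at 0.60), heat shock (5 rose, with hsp-110 at 0.40), antimicrobial peptides (9 rose and 1 fell) and the histone modifiers (6 rose, with jmjd-3.3 at 0.38). Downward they were cuticle collagens (47 fell and 1 rose), detoxification enzymes (68 fell and 22 rose), propionate shunt and vitamin B12 genes (10 fell and 2 rose), muscle genes (9 fell), nuclear hormone receptors (52 fell and 13 rose) and lysozymes, lectins and saposins (52 fell and 19 rose). Rises and falls adjusted over the list alone were 13 and 3 for histones, 7 and 0 for heat shock, 9 and 2 for antimicrobial peptides, 7 and 0 for histone modifiers, 1 and 49 for collagens and 24 and 68 for detoxification enzymes. They were 2 and 12 for the vitamin B12 list, 0 and 9 for muscle, 13 and 50 for nuclear hormone receptors and 20 and 52 for lysozymes, lectins and saposins. Their camera adjusted p ranged from 1.12e-07 for collagens to 0.0258 for lysozymes, and from 0.49 to 0.638 with an estimated correlation. The call of the lysozyme list ended with centred arrays (camera adjusted p = 0.0614), where its median was -0.109 against -0.043 as deposited. Centring moved the median of all probe sets by -0.066. The call of antimicrobial peptides ended without replicate 2 of utx-1 RNAi without males (0.0585). Not all of these lists passed in both backgrounds. The lists of muscle, nuclear hormone receptors, histone modifiers, and lysozymes, lectins and saposins passed under utx-1 RNAi and not without RNAi. Muscle genes averaged 7.64 without and 7.62 with males in the arrays without RNAi. Except for nuclear hormone receptors, these lists also passed in the interaction. Heat shock and antimicrobial peptides passed without RNAi and not under utx-1 RNAi, and fat metabolism passed in neither. In the averaged comparison 6032 probe sets changed, 3242 higher and 2790 lower, and with centred arrays 2487 were higher and 5145 lower. Without replicate 1 of utx-1 RNAi with males the count was 4021.

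The next comparison asks what utx-1 RNAi changes without males (3 arrays against 3). Apart from utx-1, the falls were the saposin-like gene spp-12 (-2.02 ± 0.29), ugt-66 (-1.29 ± 0.19), try-5 (-1.21 ± 0.19) and clec-4 (2-fold), each with adjusted p = 0.0308. The gene try-5 encodes a protease of seminal fluid. Further falls were C32H11.4 (-0.99), nhr-10 (-0.84), lact-1 (-0.82), E03H12.7 (-0.77), F49F1.5 (-0.76), nhr-11 (-0.68) and the kinesin gene unc-104 (-0.62, adjusted p = 0.0431). The rises were Y47H10A.5 (1.05 ± 0.16, adjusted p = 0.0308), igcm-4 (0.90 ± 0.08, adjusted p = 0.0011), the neprilysin gene nep-22 (0.87), clec-10 (0.81), F10D2.10 (0.76), F19C7.2 (0.72), the tyrosyl-tRNA synthetase gene yars-1 (0.63) and F52G2.3 (0.60). Of the 20 genes named here with utx-1, 18 lost their call in at least 1 alternative, 15 of them with the replicate block, and only igcm-4 and utx-1 lost it in none. Of the other genes followed, sod-3 was at 0.24 (adjusted p = 0.225), jmjd-3.1 at 0.31 (adjusted p = 0.189), unc-25 at -0.47 (adjusted p = 0.145) and glp-1 at 0.08 (adjusted p = 0.864).

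Of 147 cuticle collagens 1 fell with utx-1 RNAi without males, col-142 by 0.53 (adjusted p = 0.0437, lost in 13 of 20 alternatives and 0.15 at the highest, with the replicate block), also adjusted over the list alone (median -0.16, camera adjusted p = 3.85e-05; adjusted p = 0.951 with an estimated correlation). Of 14 male somatic genes 1 fell, also adjusted over the list alone, which was try-5 (median -0.18, camera adjusted p = 0.0016; adjusted p = 0.467 with an estimated correlation). In 3 more lists limma passed 0 members over all probe sets: 33 proteasome genes (median 0.08, camera adjusted p = 7.25e-05), 23 major sperm protein genes (median -0.33, camera adjusted p = 0.00119) and 80 hedgehog-related genes (median -0.093, camera adjusted p = 0.0377), each with adjusted p = 0.951 with an estimated correlation. Their calls ended without replicate 1 of glp-1 without males for the proteasome (0.0536) and hedgehog-related genes (0.0863), and without replicate 3 for major sperm proteins (0.0532). Adjusted over the list alone, 1 hedgehog-related gene rose and 2 fell, and 0 members of the other lists passed. At an unadjusted p under 0.05 limma had 7 proteasome genes higher, 9 major sperm protein genes lower, and 1 hedgehog-related gene higher and 21 lower. In all, 37 probe sets changed, 8 higher and 29 lower, against 3824 at an unadjusted p under 0.05. The count was 6 with the replicate block and 5 to 59 with 1 array left out. It was 7, 21 and 16 without replicates 1, 2 and 3 of glp-1 without males, 8, 5 and 6 without those of utx-1 RNAi without males, and 20 and 59 without replicates 2 and 3 of glp-1 with males. The split was 36 higher and 28 lower with centred arrays and 42 and 46 with cyclic loess.

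With males present, the arrays of utx-1 RNAi (n = 2) were compared with those without RNAi (n = 3). Of the 12 rises named, 5 are in the oocyte and eggshell list and 2 in the germ cell list. They were cpg-2 (5.94 ± 0.28, adjusted p = 8.45e-08), cpg-1 (5.88 ± 0.28), sip-1 (5.81 ± 0.37), clec-87 (5.57), cbd-1 (5.34), mesp-1 (5.01), mex-5 (4.76), rme-2 (4.75), W05F2.3 (4.64), cey-2 (4.62), puf-7 (4.57) and the oocyte surface gene egg-1 (4.52). The gene glp-1 rose by 1.48 ± 0.19 (adjusted p = 0.00022). The largest falls were F09C6.10 (-2.93 ± 0.69, adjusted p = 0.0138), K12H6.9 (-2.85), fipr-17 (-2.65), C48B4.12 (-2.65), K03D3.5 (-2.63), clec-197 (-2.62), ins-31 (-2.61), T26A8.3 (-2.53), ZK1290.11 (-2.34), clec-94 (-2.31), C35B1.3 (-2.28) and clec-219 (-2.27). Of these 12 falls 11, all but clec-94, lost their call without replicate 1 of utx-1 RNAi with males, with an adjusted p of 0.0674 for T26A8.3 to 0.189 for ins-31. With only the 2 groups compared 10 lost it and with the trended prior 9, while the 12 rises lost it in none. All 12 falls but C48B4.12 are among the 13 probe sets that were high in replicates 1 and 2 of glp-1 with males. In all, 3165 probe sets changed, 2021 higher and 1144 lower. With centred arrays 1822 were higher and 3190 lower, and without replicate 1 of utx-1 RNAi with males 1476 changed.

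Of 29 germ cell genes 28 rose with utx-1 RNAi in the presence of males (29 adjusted over the list alone; median 2.19, camera adjusted p = 6.89e-39; adjusted p = 0.0815 with an estimated correlation), as did 11 of 13 oocyte and eggshell genes, also adjusted over the list alone (median 3.23, camera adjusted p = 2.69e-17; adjusted p = 0.13 with an estimated correlation). Of 23 major sperm protein genes 8 fell (21 adjusted over the list alone; median -0.67, camera adjusted p = 8.5e-07; adjusted p = 0.586 with an estimated correlation), such as msp-59 by 1.24. Of 14 male somatic genes 3 fell (4 adjusted over the list alone; median -0.17, camera adjusted p = 0.0131; adjusted p = 0.513 with an estimated correlation), with try-5 at -1.27. Of 23 muscle genes 9 fell (15 adjusted over the list alone; median -0.48, camera adjusted p = 5e-06; adjusted p = 0.586 with an estimated correlation), with unc-54 at -0.80 and lev-11 at -0.70. Of 48 neuropeptide-like genes 8 fell, also adjusted over the list alone (median -0.20, camera adjusted p = 0.00114; adjusted p = 0.586 with an estimated correlation), and of 24 insulin-like genes 3 fell, also adjusted over the list alone (median -0.25, camera adjusted p = 0.0148; adjusted p = 0.586 with an estimated correlation): ins-31, ins-35 (-0.72) and ins-22 (-0.56). Of 1248 chemoreceptor genes 33 fell (1 adjusted over the list alone), a smaller share than the 1144 that fell of all 22548 probe sets. Their median was -0.073, or -0.144 with centred arrays and -0.012 with cyclic loess. That of all probe sets was close to it, at -0.058, -0.128 and -0.0047 in the same order. The chemoreceptor list averaged 2.84 in glp-1 with males and 2.76 in utx-1 RNAi with males, below the array medians. Its camera adjusted p was 0.00931, or 0.11 with cyclic loess and 0.000583 at the lowest over the other alternatives (adjusted p = 0.609 with an estimated correlation). Further lists past the threshold downward were other sperm genes (7 fell and 2 rose of 50, with ssp-34 at -0.43), FMRFamide-like peptides (2 fell of 25, with flp-4 at -0.45) and neurons (3 fell of 21, with cat-2 at -0.46). So were hedgehog-related genes (5 fell and 1 rose, with grl-10 at -0.81 and ptr-2 at 2.63), nuclear hormone receptors (15 fell and 4 rose, with nhr-23 at 1.11), collagens (13 fell), detoxification enzymes (25 fell and 6 rose) and lysozymes, lectins and saposins (30 fell and 4 rose). The shares of hedgehog-related genes and nuclear hormone receptors that fell lay near that of all probe sets. The proteasome list rose (2 members). Rises and falls adjusted over the list alone were 2 and 9 for other sperm genes, 0 and 2 for FMRFamide-like peptides, 0 and 6 for neurons, 1 and 4 for hedgehog-related genes and 1 and 8 for nuclear hormone receptors. They were 0 and 6 for collagens, 6 and 32 for detoxification enzymes, 4 and 28 for lysozymes, lectins and saposins, and 0 and 0 for the proteasome, where limma had 9 members higher at an unadjusted p under 0.05. The camera adjusted p of these lists ranged from 2.19e-06 for collagens to 0.0197 for neurons, and from 0.586 to 0.688 with an estimated correlation. The call of neurons ended without replicate 1 of utx-1 RNAi with males (adjusted p = 0.0874), and those of male somatic genes and insulin-like peptides without its replicate 3 (0.068 for each). Single calls that ended without replicate 1 were those of ins-35 (0.081), ins-22 (0.068), lev-11 (0.0699), ssp-34 (0.12), flp-4 (0.0768) and cat-2 (0.183). For the 15 histone modifiers 4 rose and 1 fell (5 and 1 adjusted over the list alone), the median was 0.22 and the test pointed up (camera adjusted p = 0.00483; adjusted p = 0.586 with an estimated correlation), whereas the mean was -0.024 with utx-1 itself in the list.

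The interaction asks whether the males effect differs between the backgrounds, and it passed for 1725 probe sets, 1448 more positive and 277 more negative under utx-1 RNAi. The largest positive values were those of sip-1 (6.21 ± 0.49, adjusted p = 7.26e-06), cpg-2 (6.18 ± 0.37, adjusted p = 1.67e-06) and cpg-1 (6.13 ± 0.38, adjusted p = 1.86e-06). For glp-1 it was 1.40 ± 0.26 (adjusted p = 0.00463) and for utx-1 at its brighter probe set 2.37 ± 0.54 (adjusted p = 0.0179, or 0.000718 to 0.0956 over the alternatives, the highest without replicate 1 of utx-1 RNAi with males). At the dimmer probe set it was 0.32 ± 0.14 and did not pass (adjusted p = 0.226). The value for sod-3 was -0.55 ± 0.14 (adjusted p = 0.0338, or 0.00901 to 0.174 over the alternatives, the highest again without that replicate), and those of ins-7 (-0.27, adjusted p = 0.674) and ins-11 (-0.34, adjusted p = 0.618) did not pass. Of 29 germ cell genes 27 passed upward (28 adjusted over the list alone; camera adjusted p = 2.15e-38; adjusted p = 0.0845 with an estimated correlation). Of the 1725 probe sets, 1440 had changed with males under utx-1 RNAi and had not passed without RNAi, and 215 had changed without RNAi. With centred arrays, which moved the median of all probe sets by -0.11, 1202 were higher and 1185 lower, and without replicate 1 of utx-1 RNAi with males the count was 1137.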

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

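The count of germ line transcripts in single glp-1 arrays and the tests of carried-over males, of missing knockdown and of males in the glp-1 arrays were chosen only after the result was seen, while the test of embryonic genes was written before its result and after the main lists had been seen.

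The males effect differed between the backgrounds, by the interaction test, for 1725 probe sets. Past camera's threshold for the interaction were germ cells (median 2.08), oocytes and eggshell (3.40) and modifiers of histone H3 lysines 27 and 4 (0.24) upward. Downward were muscle (-0.42), major sperm proteins (-0.38), neuropeptide-like proteins (-0.16), FMRFamide-like peptides (-0.12), detoxification enzymes (-0.099) and lysozymes, lectins and saposins (-0.088). With an estimated correlation the adjusted p was 0.0845 for germ cells, 0.11 for oocytes, 0.832 for histone modifiers and 0.858 for the other lists. With centred arrays the adjusted p was 0.0686 for major sperm proteins, 0.0926 for detoxification enzymes and 0.104 for lysozymes, lectins and saposins. Over the other alternatives it ranged from 0.000425 to 0.186, from 0.000595 to 0.364 and from 0.00791 to 0.167 for these lists, the highest without replicate 2 of glp-1 with males for the first and without replicate 1 of utx-1 RNAi with males for the others. For FMRFamide-like peptides it ranged from 0.00811 to 0.167, the highest again without the latter array.

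Among single genes, the difference was positive for sip-1 (6.21), cpg-2 (6.18), cpg-1 (6.13), clec-87 (5.77), cbd-1 (5.57), mesp-1 (5.18), rme-2 (5.05), W05F2.3 (4.84), cey-2 (4.82), mex-5 (4.74), puf-7 (4.70) and F18A1.7 (4.66). It was negative for T26A8.3 (-2.62), clec-94 (-2.22), C16C8.7 (-1.73), F42C5.3 (-1.53), C16C8.9 (-1.51), pals-29 (-1.35), B0507.8 (-1.32), Y82E9BL.9 (-1.18), egl-3 (-1.17), F46A8.7 (-1.17), rabr-4 (-1.15) and pals-6 (-1.15). For egl-3, which encodes a proprotein convertase, the brightest probe set gave -0.68 (limma adjusted p = 0.161). The 12 positive calls held in all alternatives and 6 of the negative ones ended in some, with a highest adjusted p of 0.147 for T26A8.3, 0.063 for F42C5.3 and 0.106 for pals-6, all without replicate 1 of utx-1 RNAi with males. For clec-94 (0.125) and C16C8.7 (0.0948) it was highest with the trended prior and for B0507.8 (0.0835) without replicate 3 of utx-1 RNAi with males. Both T26A8.3 and clec-94 were highest in replicates 1 and 2 of glp-1 with males. In replicate 3 they read 3.91 and 4.72, against 3.16 and 3.87 at the highest in the other groups.

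The first pattern is the germ line transcripts in both arrays of utx-1 RNAi with males, where 257 probe sets lay at least 1.5 above every other array. A part of these was also raised in glp-1 with males: 14 lay at least 1 above all arrays without males in replicate 1, 2 in replicate 2 and 0 in replicate 3, with iff-1 at 7.06 against 4.74, cpg-3 at 5.71 against 3.93 and clec-91 at 5.59 against 3.93 in replicate 1. In the same array cpg-2 and cpg-1 read 3.15 and 2.93, within their range in glp-1 without males, and the median of the 257 lay 0.0816 above glp-1 without males, against 2.87 and 2.70 in the arrays of utx-1 RNAi with males. What raised that part was not tested. As the source of the oocyte and eggshell transcripts in the arrays of utx-1 RNAi with males, carried-over males or their sperm are argued against. Males do not make the genes of that list, and its median change was 3.34 while that of the major sperm proteins was -0.086. That all worms of these arrays lacked the knockdown is argued against, since utx-1 at its dimmer probe set lay at -2.15 against glp-1 with males. At that probe set 22.5% of the signal was left with males, against 18.1% without males. At the brighter one 5.51% was left with males, against 1.07% without. A minority of worms without knockdown was not tested and stays open. Embryos or fertile worms in the collected material may account for the pattern and stay open. The 51 early zygotic genes had a median of 0.111, above 10000 random lists matched on level (95% of them from -0.079 to 0.018). The brightest of these genes, sdz-27, lay at 11.77 with and 11.69 without males. Of the 51 genes, 5 rose (sdz-35, die-1, tbx-9, vet-6 and vet-2) and 2 fell (sdz-24 and nob-1). Over all 22548 probe sets 2671 rose and 2036 fell, which are larger shares. The largest rise among the 51 was that of vet-2, by 0.997, against the median of 3.34 for oocyte and eggshell genes. The zygotic list therefore does not single out embryos from other germ line material. A biological difference, such as germ line growth in glp-1 worms under utx-1 RNAi with males, stays open and untested, and it rests on the 2 arrays of this group. Without an empty-vector group, utx-1 knockdown could not be told apart in it from RNAi treatment as such or from food.

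The second pattern, picked out after the values were seen, is the 13 probe sets at least 1.5 higher in replicates 1 and 2 of glp-1 with males than in any other array: fipr-16, C35B1.3, clec-219, K03D3.5, K12H6.4, F09C6.10, ins-31, T26A8.3, K12H6.9, ZK1290.11, clec-94, clec-197 and fipr-17. Of all 55 pairs of arrays, only this one and the pair of utx-1 RNAi with males (257 probe sets) had over 10. The median excess over replicate 3 was 2.42, and replicate 3 itself lay 0.859 above the mean of the other groups. Males with sperm among the collected worms could give such a pattern and stay open: the major sperm protein list was 0.305 higher in those replicates, and no array known to hold sperm was there to show how far the list would move. No biological explanation was tested.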

How the results depend on the processing

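The fit without both arrays of utx-1 RNAi with males was chosen only after the result was seen. It gave 2732 probe sets for males without RNAi and 40 for utx-1 RNAi without males. With the replicate block, 1552 changed with males without RNAi and 6 with utx-1 RNAi without males, and the other counts were 3564, 4829, 2302 and 1303 in the order males under utx-1 RNAi, averaged, utx-1 RNAi with males and interaction. Across all probe sets the replicate numbers of the titles did not pair the arrays. Deviations from the group means correlated at -0.352 to 0.0506 in the 15 pairs of arrays with the same number, and 0 arrays correlated best with their own number. The differing numbers of the descriptions were not tried, and whether arrays with different numbers share a batch was not tested. Among the 257 germ line probe sets, however, replicate 2 had the highest median in each of the 3 groups with n = 3. It lay 0.219, 0.235 and 0.184 above the mean of glp-1 without males in glp-1 without males, glp-1 with males and utx-1 RNAi without males. In replicates 1 and 3 of these groups the highest was 0.0816. A batch tied to the replicate number stays open for these probe sets. For utx-1 RNAi without males the count was 96 with a trended and robust prior, 64 with centred arrays, 88 with cyclic loess, 65 with array weights and 18 with only the 2 groups compared. Centring gave 7565 for males under utx-1 RNAi and 5012 for utx-1 RNAi with males. It moved the median of all probe sets by -0.12 and -0.071 in these comparisons. The added calls were falls, with 5553 and 3190 lower against 2036 and 1144 as deposited. For the other counts named here the cause was not tested, apart from fewer arrays in the fit of only the 2 groups compared. All other counts in these settings, with dim probe sets left out and with 1 probe set per gene, lay within 1.5 times those reported.

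Leaving out each array in turn gave 1362 to 2732 probe sets for males without RNAi, 2028 to 4867 for males under utx-1 RNAi, 4021 to 5855 averaged, 5 to 59 for utx-1 RNAi without males, 1476 to 3218 for utx-1 RNAi with males and 1137 to 1706 for the interaction. The lowest counts of males under utx-1 RNAi, averaged, utx-1 RNAi with males and interaction all came without replicate 1 of utx-1 RNAi with males, where the lone array left is assumed to vary like the other groups. For males without RNAi the count was 1362 without replicate 1 of glp-1 without males, and 1678 and 1524 without replicates 2 and 3 of glp-1 with males. For utx-1 RNAi without males the count was 7, 21 and 16 without replicates 1, 2 and 3 of glp-1 without males, 8, 5 and 6 without those of utx-1 RNAi without males, and 20 and 59 without replicates 2 and 3 of glp-1 with males. No named gene or list past the threshold turned its direction in any setting, and 165 values that passed in neither setting changed sign. The genes with the largest changes and those followed in every comparison lost their call 28 times with the block, 24 times with the trended prior, 20 times with only the 2 groups compared and 220 times over the 11 arrays left out. Named list members past the threshold lost it in at least 1 alternative for 37 of 99 with males without RNAi, 44 of 109 with males under utx-1 RNAi, 11 of 117 averaged, 2 of 2 with utx-1 RNAi without males, 50 of 88 with utx-1 RNAi with males and 17 of 47 in the interaction. The estimated correlation ended all 71 list calls, and centring ended 6 and added 5. Dim probe sets lie close to background, which limits what they can show. Leaving out 1 array ended 20 of the list calls at least once (47 losses over the 11 arrays), with the highest adjusted p at 0.364 for detoxification enzymes in the interaction, without replicate 1 of utx-1 RNAi with males.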

Other observations

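The grouping tests of this part were written before their results. The near-floor condition in the test of acdh-1 was chosen only after the result was seen.

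The list of RNAi and intracellular pathogen response genes did not pass for males under utx-1 RNAi (camera adjusted p = 0.526). Of its 47 members 11 rose and 5 fell (11 and 6 adjusted over the list alone), the median was -0.026, and the mean of 0.11 and the test pointed up. The males effect was 2.83-fold for eri-9 and, on the log2 scale, 1.40 for rde-3 and 1.38 for ergo-1 (limma adjusted p = 3.39e-07, 5.14e-06 and 3.29e-05), and pals-31 fell by 0.75. Members of other lists that rose were rpl-11.1 (2.16), ptr-2 (2.97) and the F-box gene fbxa-215 (3.26). At an unadjusted p under 0.05 limma had 2 of 75 ribosomal protein genes higher and 0 lower. Of 80 hedgehog-related genes it had 4 higher and 9 lower, and of 310 F-box genes 37 higher and 37 lower. Whether the rises named here belong to the germ line signal of the same 2 arrays was not tested. The RNAi and pathogen response list did not pass for males without RNAi either (camera adjusted p = 0.102), where 7 members rose, among them pals-5 (1.57), pals-4 (1.09) and pals-32 (0.94), and 1 fell (8 and 1 adjusted over the list alone).

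Different bacterial food of the RNAi plates is a possible explanation for the changes of utx-1 RNAi without males. The gene acdh-1, whose level follows the vitamin B12 content of the bacteria, was at -0.155 ± 0.073 (adjusted p = 0.31), with a 95% interval from -0.314 to 0.0046. That met the bound set in advance against this explanation, but the bound was wrong because it ignored the level: acdh-1 lay at 2.91 without RNAi and 2.76 with utx-1 RNAi, below the median of all values of 3.88, where a fall may not be seen. The interval speaks only against a rise of acdh-1. Food therefore stays open. The propionate shunt and vitamin B12 list did not pass (camera adjusted p = 0.583, median -0.034, 0 rose and 1 fell of 22, and 0 and 2 adjusted over the list alone). At an unadjusted p under 0.05 limma had 0 higher and 4 lower.

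For males averaged over both backgrounds, 1 of 100 splits of the arrays, the real one, gave as many as 6032 probe sets. The highest other split gave 1656, and in it only glp-1 arrays had changed groups. The share under 0.05 argues against a chance split of the arrays. It cannot speak to a batch or to carried-over material, which would follow the real groups. The other comparisons allow 10 splits, too few for a share under 0.05. The real split was the only 1 of 10 to reach its count in each: 2661 against 0 for males without RNAi, 4707 against 1 for males under utx-1 RNAi, 37 against 0 for utx-1 RNAi without males and 3165 against 30 for utx-1 RNAi with males.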
